A study of Mus musculus with 28 samples.

How the data were processed

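RNA was measured in dendritic cells sorted from the spleen of C57BL/6 mice. The labels name conventional dendritic cells of type 1 (cDC1), of type 2 (cDC2) and a population called hybrid DC, from 5 genotypes in 2 experiments with 2 biological replicates per group (28 libraries in 14 groups). Per the labels, total RNA was isolated with a NucleoSpin RNA XS kit, 10 ng with an integrity number above 9.0 went into a SMARTer Ultra Low kit, and 12 to 15 cycles of PCR followed. The sort gates are not given in the labels.

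The deposited values are expected counts, which are estimated reads per Ensembl gene, in 1 table per experiment. The submitters' notes name bcl2fastq, DRAGEN and edgeR without versions, settings, genome build or annotation. Of the deposited values 10.8% in experiment 1 and 10.2% in experiment 2 were not whole numbers, none was negative, and library totals differed, so the tables hold estimates that had not been scaled. 287 lines of each table repeated another line exactly, and 1 of each was kept, leaving 55487 of 55774. Of these gene IDs 55141 (99.4%) occur in GENCODE release M21, which gave the coordinates on GRCm38. Every column matched 1 library, and replicates had not been pooled. Symbols that differed between the 2 tables were taken from experiment 1 by gene ID. Values were rounded to whole counts.

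Each experiment was fitted with edgeR 4.0.16 in R 4.3.3, with all its libraries and 1 coefficient per group, so that all groups shared the estimate of the spread. Genes with few counts were removed by filterByExpr with the groups, and TMM factors (0.914 to 1.113 in experiment 1, 0.962 to 1.032 in experiment 2) scaled the libraries. Robust quasi-likelihood F tests (glmQLFit and glmQLFTest) were made per contrast, on 16037 genes with 8 residual degrees of freedom in experiment 1 and on 14504 genes with 6 in experiment 2. Adjusted p is the Benjamini-Hochberg value over all genes of a contrast, with a threshold of 0.05. The median biological coefficient of variation was 0.158 and 0.138. The standard error of a log2 fold change is its size divided by the square root of F. CPM are counts per M of the TMM-scaled library, and log2 CPM used a prior count of 2. Values are group means with the SD of 2 libraries.

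The contrasts were cDC1 against cDC2 in WT mice, each altered genotype against its control within a cell type, hybrid cells against cDC1 and cDC2 of the same genotype, H/H against H/+ hybrid cells, and the difference between the Nfil3 effects in hybrid cells and cDC1 as an interaction. The contrasts, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Contrasts added afterwards were H/H against H/+ in cDC1 and in cDC2, the difference between the H/H effects in cDC1 and cDC2, the difference between the Nfil3 and Zeb2 effects, and Zeb2 -165D123 hybrid cells against H/H cDC1. The experiments were not pooled except as an alternative. Whether equal replicate numbers mark cells from 1 animal is not stated in the labels, so no pairing was assumed.

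Genes are named by a fixed rule. Named in each contrast are the fixed genes Irf8, Batf3, Irf4, Zeb2, Nfil3, Id2, Zbtb46, Tcf4, Xcr1, Cd8a, Sirpa and Itgam. Added are the 8 largest rises and 8 largest falls among genes past the threshold that changed at least 2-fold, had at least 10 CPM in the higher group and did not overlap between replicates of the groups, without predicted genes, pseudogenes and receptor segments. Of each list with an adjusted camera p below 0.05 or at least 3 members past the threshold, up to 4 members with the largest change are added. Above 30 genes per contrast the rest are summarised. For the interactions the fixed genes and those with the smallest p are named. Beyond this rule, and after their values were seen, the list members Itgae in the WT contrast, C1qb in H/H hybrid cells, and Itgae, Gcsam, Cx3cr1, Mki67, Bub1, Ccna2, Top2a, C1qa, C1qc and Mertk in the Zeb2 contrast were named. Genes beyond both parents in the closing section were also chosen afterwards. 1 gene that the rule names is not reported here.

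Gene lists written from general knowledge covered markers of cDC1, cDC2, pDC, B cells, T cells, NK cells, monocytes and macrophages, neutrophils, erythroid cells and platelets. Others covered dendritic cell transcription factors, MHC class I and class II presentation, interferon-stimulated genes, maturation, cell cycle, immediate early and heat shock genes, pattern recognition receptors, chemokines and migration receptors, uptake of dead cells, circadian clock and PAR bZIP genes, the C/EBP family, ribosomal proteins and mitochondrially encoded genes. Some genes stand in more than 1 list. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, with p adjusted over all lists and planned contrasts of an experiment (240 and 168 tests). Members past the threshold are counted over all genes and with p adjusted over the list alone.

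The position of a group is the mean log2 CPM of the cDC1 list minus that of the cDC2 list. A lineage signature was taken from genes that passed and changed at least 2-fold between WT cDC1 and WT cDC2. Agreement between experiments and between the Nfil3 and Zeb2 effects is given as correlations across genes and as shared calls, with 30 simulated pairs of unchanged groups for the controls that the latter share.

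Library totals were 23.4 to 38.2 M counts in experiment 1 and 17.5 to 22.7 M in experiment 2, with 20326 to 23682 genes seen and 0.94 to 2.07% of counts from mitochondrial genes. A floor of 3 counts stood for 0.0786 to 0.128 CPM per library in experiment 1 and 0.132 to 0.171 in experiment 2. Replicates correlated at 0.968 to 0.984 (Pearson, log2 CPM), and their spread was 9.62 to 47.7 times that of counting alone (chi-square per degree of freedom), so counting noise was a small part of it. In experiment 1 replicate 1 of each group held Y-linked transcripts and replicate 2 held Xist. In experiment 2 the WT and H/H libraries held Y-linked transcripts, and each Nfil3-/- and Zeb2 -165D123 group held 1 library of each kind.

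The steps were tested on simulated data, with 200 changed genes (50 at each fold) in the H/H cDC1 contrast of experiment 1 (14431 genes) and the Nfil3 contrast in cDC1 (13784 genes). At 2-fold 90% and 90% were recovered, at 4-fold 96% and 100%, at 0.5-fold 88% and 90%, and at 0.25-fold 98% and 100%. False calls were 5.6% and 2.6%. Alternatives were DESeq2 1.42.0, RLE factors, no filter, a filter at 1 CPM, only the groups compared, a replicate block, a block within genotype, glmTreat at 1.5-fold, both experiments in 1 fit, leaving out each library, and other scales and set tests. A term for Xist libraries, and leaving out the 3 Xist libraries of experiment 2, were added after the data were seen. No library was left out of the results given. Changes in cell numbers, and whether a transcript from an altered allele makes protein, cannot be read from these data.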

Results

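Bulk RNA-seq read counts per gene were available for dendritic cells sorted from mouse spleen. The cells were conventional dendritic cells of type 1 (cDC1), known for cross-presentation of antigen to CD8 T cells, those of type 2 (cDC2), known for presentation to CD4 T cells, and a population named hybrid DC. The mice were wild type (WT), heterozygous (H/+) or homozygous (H/H) for an altered allele of an Irf8 enhancer at +32 kb, named +32H. H/H mice that lacked Nfil3 (H/H Nfil3-/-) and H/H mice with an altered Zeb2 enhancer at -165 kb (H/H Zeb2 -165D123) were also used. Experiment 1 held 16 libraries in 8 groups, namely cDC1 and cDC2 of WT, H/+ and H/H mice and hybrid cells of H/+ and H/H mice. Experiment 2 held 12 libraries in 6 groups, namely cDC1 of WT, H/H and H/H Nfil3-/- mice and hybrid cells of H/H, H/H Nfil3-/- and H/H Zeb2 -165D123 mice. Each group had 2 biological replicates. Expression is in counts per M (CPM), mean ± SD (SD, n = 2 libraries). Each gene named as changed had both libraries of one group above both libraries of the other, unless stated otherwise.

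Irf8, a transcription factor that cDC1 require, is gene ENSMUSG00000041515 (GRCm38, chromosome 8, 120736358 to 120756694, plus strand). In experiment 1 it stood at 2270 ± 439 CPM in WT cDC1, 1156 ± 92 in H/+ cDC1 and 834 ± 4.26 in H/H cDC1. In cDC2 the order ran the other way, with 48.4 ± 0.681 CPM in WT, 60.4 ± 4.61 in H/+ and 97.9 ± 16.4 in H/H cells. Hybrid cells lay between these populations, at 399 ± 7.85 CPM in H/+ and 562 ± 25.5 in H/H mice. Zeb2, a zinc finger repressor (ENSMUSG00000026872, chromosome 2, 44983632 to 45117395, minus strand), stood at 42.8 ± 5.89 CPM in H/H hybrid cells of experiment 2 and at 14.9 ± 6.55 in Zeb2 -165D123 hybrid cells. Nfil3, a basic leucine zipper factor (ENSMUSG00000056749, chromosome 13, 52967209 to 52981073, minus strand), stood at 36.3 ± 0.871 CPM in H/H cDC1 and 48.4 ± 9.76 in H/H hybrid cells. In Nfil3-/- cells it stood at 3.22 ± 0.654 CPM in cDC1 and 5.66 ± 0.0537 in hybrid cells, each library below every Nfil3-intact library of experiment 2.

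**Figure D1:**
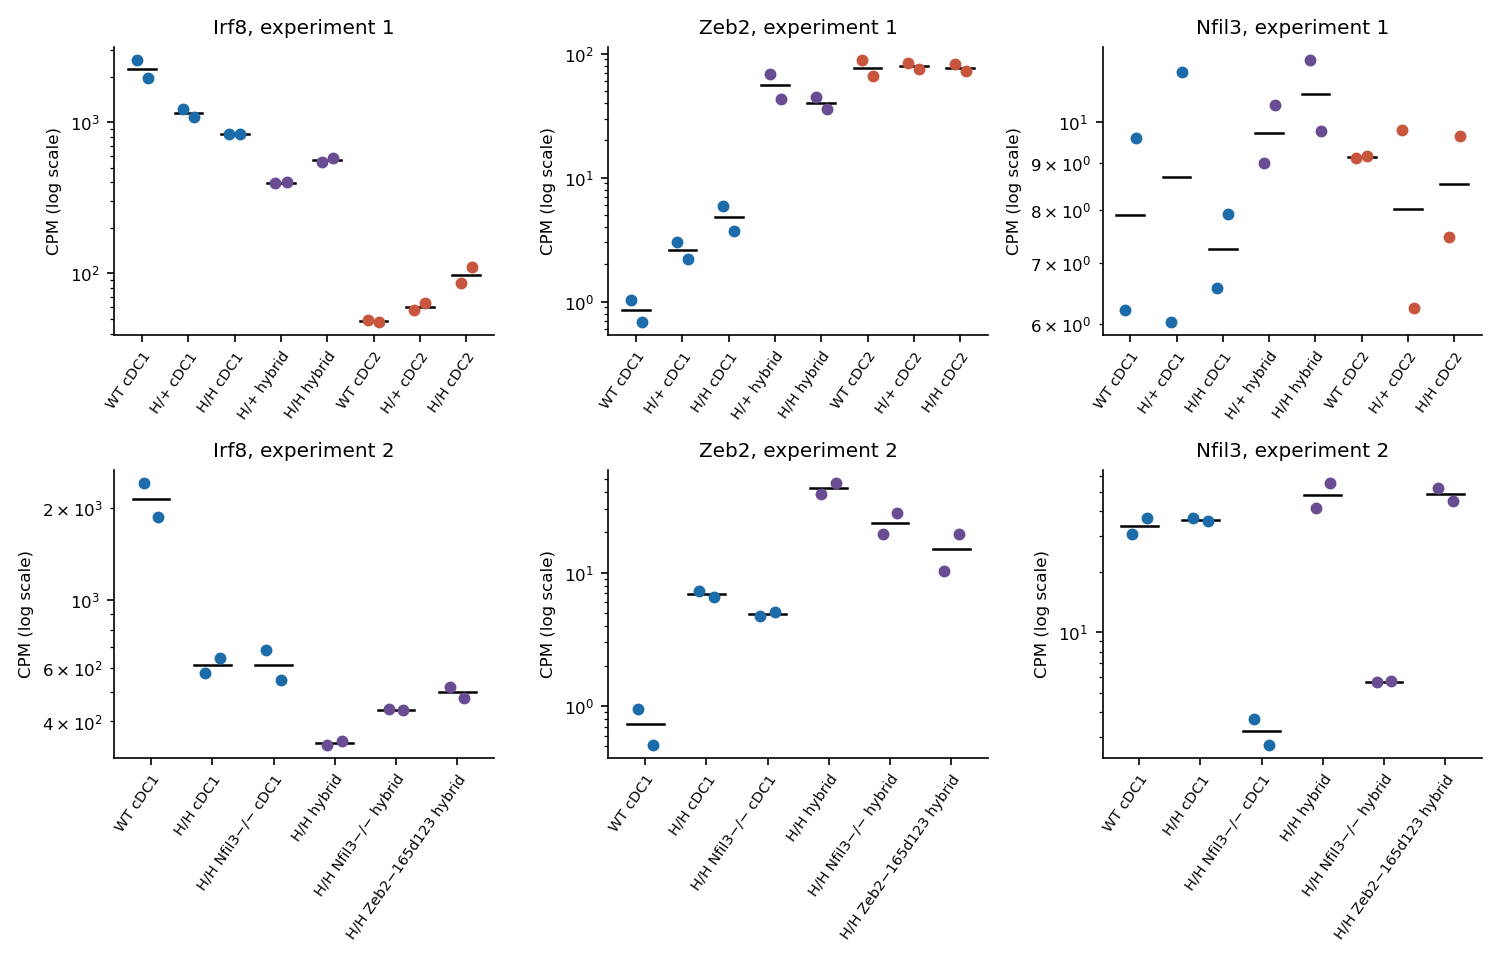
CPM on a log axis of Irf8, Zeb2 and Nfil3 per library (points) with the group mean (line) for the 8 groups of experiment 1 (top) and the 6 groups of experiment 2 (bottom), with cDC1 in blue, hybrid cells in purple and cDC2 in red. Mean Irf8 fell from 2270 CPM in WT cDC1 to 834 in H/H cDC1 and rose from 48.4 in WT cDC2 to 97.9 in H/H cDC2.

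The first comparison set the normal distance between the lineages, WT cDC1 against WT cDC2. All 28 cDC1 markers were higher in cDC1, among them the chemokine receptor Xcr1 (934 ± 7 against 5.45 ± 0.32 CPM), the coreceptor chain Cd8a (621 ± 56.1 against 24.8 ± 3.22 CPM) and the integrin chain Itgae (CD103, 87.8 ± 0.6 against 0.884 ± 0.529 CPM). Of the 26 cDC2 markers, 23 were lower in cDC1 (24 adjusted over the list alone) and 1 was higher, with Sirpa at 1.03 ± 0.209 against 256 ± 7.11 CPM and Itgam (CD11b) at 0.858 ± 0.546 against 94.7 ± 10.5 CPM. Among lineage factors Irf8 (46.9-fold), Batf3 (2.05-fold), which partners with IRF proteins, and Id2 (3.48-fold), an inhibitor of E proteins, were higher in cDC1. Irf4 (39.3-fold), Zeb2 (91.2-fold) and the E protein Tcf4 (4.23-fold) were higher in cDC2. Nfil3 and Zbtb46, a factor shared by conventional dendritic cells, did not pass the test (log2 fold changes from -0.21 to -0.08, adjusted p from 0.593 to 0.6). The largest rises in cDC1 were in Gpr141b, Gcsam, Dkk3, Gramd2, Cd207 (langerin), Clec4b2 and Ifi205 (221- to 547-fold), and Gpr33 stood at 16.4 ± 1.97 CPM against 0 counts in cDC2. The largest falls were in Sirpb1a, Clec4a4, Ryr3 and Sirpb1c (425- to 1060-fold). Tlr5, Cdhr3 and Pram1, at 17.8, 18.6 and 26.1 CPM in cDC2, had 1 to 3 counts over the WT cDC1 group, and Mmp9, at 19.6 CPM in cDC2, had 0. A count of 0 over a group allows up to 0.0415 CPM in WT cDC2 and 0.0536 CPM in WT cDC1.

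Of the pattern recognition receptors, 4 of 25 rose and 18 fell (4 and 19 adjusted over the list alone, camera adjusted p = 3.47e-05). Of the genes of MHC class I presentation, 13 of 17 rose and 2 fell (the same counts adjusted over the list alone, camera adjusted p = 4.96e-06, adjusted p = 0.0958 with an estimated correlation). Among interferon-stimulated genes 3 of 24 rose and 17 fell (4 and 17 adjusted over the list alone, camera adjusted p = 5.18e-05, adjusted p = 0.48 with an estimated correlation), and among circadian clock and PAR bZIP genes 13 of 16 fell (14 adjusted over the list alone, camera adjusted p = 3.59e-05). The edgeR test called 7052 of 16037 genes, 3291 higher and 3761 lower in cDC1, of which 1255 and 2330 changed at least 2-fold.

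**Figure D2:**
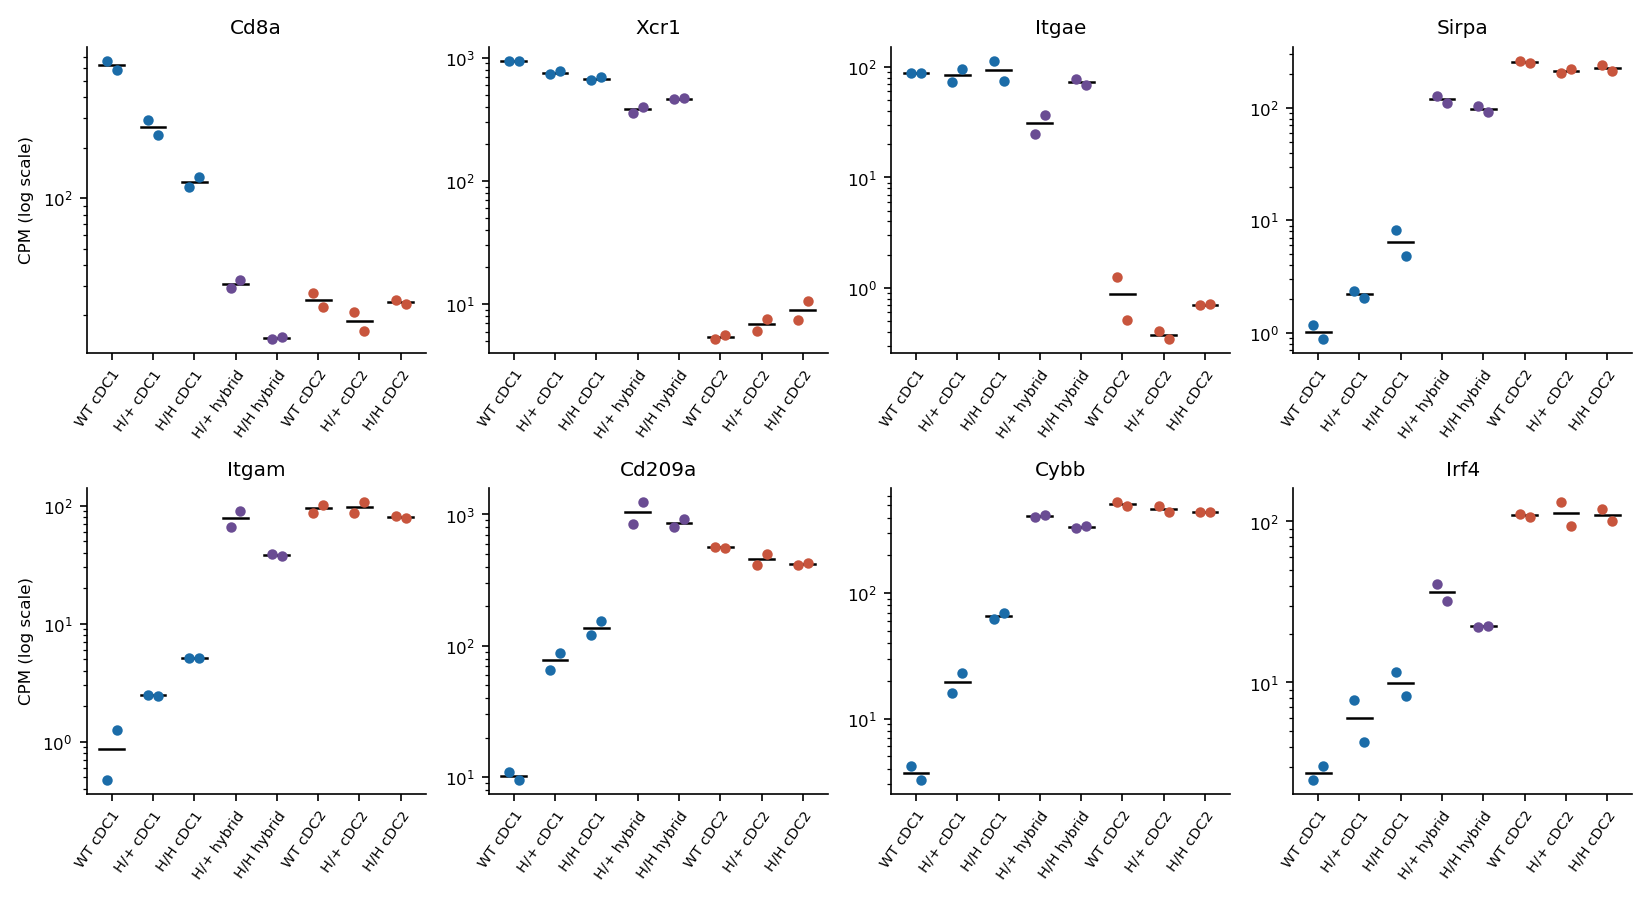
CPM on a log axis per library (points) of the cDC1 markers Cd8a, Xcr1 and Itgae, the cDC2 markers Sirpa, Itgam and Cd209a, and Cybb and Irf4, in the 8 groups of experiment 1. Mean Xcr1 was 379.7 CPM in H/+ and 465 in H/H hybrid cells, and mean Sirpa was 119 and 97.2, against 1.03 in WT cDC1.

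Does 1 copy of the altered Irf8 enhancer change cDC1? In H/+ cDC1 Irf8 was 1156 ± 92 against 2270 ± 439 CPM in WT cDC1 (-0.97 on the log2 scale, adjusted p = 0.00137). Cd8a was also lower, at 265 ± 38 against 621 ± 56.1 CPM (-1.23, adjusted p = 0.000352), as were Itm2a, Alpl, Slc25a26, Lrrc28 and Col23a1 (2.15- to 4.7-fold). Among the largest rises were the lectins Cd209a (77.3 ± 16.3 against 10.2 ± 0.99 CPM) and Cd209e, Cybb, the catalytic chain of the phagocyte NADPH oxidase (19.6 ± 5.15 against 3.72 ± 0.684 CPM), and Ifit1bl1 (28.6 ± 7.34 against 2.08 ± 0.446 CPM). Ehf, Oas1a, Cd300lf and Ifit2 rose by 3.2- to 5-fold. Itgam rose from 0.858 ± 0.546 to 2.46 ± 0.0369 CPM (adjusted p = 0.0303), and the other fixed genes did not pass (log2 fold changes from -0.39 to 1.62, adjusted p from 0.0535 to 0.926). Among cDC2 markers 7 of 26 rose (13 adjusted over the list alone, camera adjusted p = 1.04e-08). Among cDC1 markers 4 of 28 fell (7 adjusted over the list alone, camera adjusted p = 5.18e-06, adjusted p = 0.161 with an estimated correlation). Of the interferon-stimulated genes 9 of 24 rose (12 adjusted over the list alone, camera adjusted p = 2.08e-16, adjusted p = 0.126 with an estimated correlation). Of the pattern recognition receptors 3 of 25 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00218, adjusted p = 0.0661 with an estimated correlation). The test called 236 genes, 186 higher and 50 lower. The count was 597 with a term for the libraries that held Xist, and 69 and 59 without WT cDC1 replicate 1 or 2 and 95 and 457 without H/+ cDC1 replicate 1 or 2.

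With both copies altered, more genes passed in cDC1 of experiment 1. Irf8 fell to 834 ± 4.26 CPM (-1.44, adjusted p = 9.24e-06) and Cd8a to 126 ± 12 (-2.30, adjusted p = 2.43e-07). The cDC2 factors Irf4 (9.91 ± 2.43 against 2.76 ± 0.4 CPM) and Zeb2 (4.78 ± 1.54 against 0.855 ± 0.237 CPM) rose, as did Sirpa (6.49 ± 2.38 against 1.03 ± 0.209 CPM), Itgam (5.11 ± 0.0373 against 0.858 ± 0.546 CPM) and Tcf4 (0.57 on the log2 scale). Zbtb46 fell (-0.52), and Xcr1 stood at 675 ± 25.8 against 934 ± 7 CPM (adjusted p = 0.0506). Cybb (17.8-fold), Cd209a (13.5-fold) and Ms4a4c (7.71-fold) rose most outside the interferon genes Ifit1bl1, Oas1a, Ifit3 and Oasl2 (11.4- to 17.7-fold), and Ehf rose 7.18-fold. Besides Cd8a the largest falls were in Itm2a, Cd207, Alpl, Igf2r, Dcstamp, the metal transporter Slc11a1 (58.5 ± 4.59 against 211 ± 0.814 CPM) and Fndc5 (3.22- to 8.48-fold). Among cDC2 markers 14 of 26 rose (17 up and 1 down adjusted over the list alone, camera adjusted p = 2.55e-18). Among cDC1 markers 1 of 28 rose and 11 fell (1 and 15 adjusted over the list alone, camera adjusted p = 5.57e-11, adjusted p = 0.0596 with an estimated correlation). Interferon-stimulated genes were mostly higher, since 17 of 24 rose (22 adjusted over the list alone, camera adjusted p = 6.3e-34). Of the pattern recognition receptors 7 of 25 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 6.44e-06). Batf3, Nfil3 and Id2 did not pass (log2 fold changes from -0.21 to 0.17, adjusted p from 0.254 to 0.906). The test called 669 genes, 434 higher and 235 lower. Without WT cDC1 replicate 1 or 2 the count was 437 and 328, and without H/H cDC1 replicate 1 or 2 it was 372 and 406.

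Experiment 2 repeated H/H cDC1 against WT cDC1 with other libraries. Irf8 was 612 ± 50 against 2141 ± 392 CPM (-1.81, adjusted p = 4.22e-07), and Cd8a was 86.7 ± 9.21 against 515 ± 22.9 CPM (adjusted p = 5.55e-05). Sirpa (22.4 ± 0.638 against 0.704 ± 0.525 CPM), Cybb (108 ± 9.91 against 1.37 ± 0.184 CPM), Cd209a (289 ± 162 against 5.18 ± 0.674 CPM) and Tgm2, a transglutaminase (33.5 ± 2.22 against 1.94 ± 0.222 CPM), rose, with Ifit1bl1, Oas1a, Oasl2 and Nxpe4 (14.9- to 19.5-fold). Irf4, Zeb2, Itgam and Tcf4 rose (1.63- to 9.34-fold), and Xcr1 and Zbtb46 fell (1.46- to 1.51-fold). Itm2a, Pagr1a, Cd207, Igf2r, Mras, F2rl2 and Fndc5 fell by 3.78- to 15.3-fold. Among cDC2 markers 18 of 26 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 6.61e-25). Among cDC1 markers 15 of 28 fell (2 up and 19 down adjusted over the list alone, camera adjusted p = 6.78e-17, adjusted p = 0.0557 with an estimated correlation). Of the interferon-stimulated genes 16 of 24 rose (18 adjusted over the list alone, camera adjusted p = 2.71e-26, adjusted p = 0.114 with an estimated correlation). Of the pattern recognition receptors 10 of 25 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 8.23e-06, adjusted p = 0.0968 with an estimated correlation). The test called 913 genes, 634 higher and 279 lower, 581 and 571 without WT cDC1 replicate 1 or 2. Across 14347 genes tested in both experiments, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.489 and a Spearman correlation of 0.502. In both experiments 321 genes were called higher (19 by chance, from the product of the 2 shares), 135 lower (4.6 by chance) and 0 in opposite directions by edgeR.

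In cDC2 the altered enhancer had few effects, and the direction for Irf8 was the opposite. H/H cDC2 held 97.9 ± 16.4 against 48.4 ± 0.681 CPM of Irf8 in WT cDC2 (1.02, adjusted p = 0.00346). Several cDC1 genes rose with it, namely Clec9a, a receptor for dead cells (17.5 ± 2.87 against 6.64 ± 0.779 CPM), Rab7b (29.7 ± 11.7 against 5.52 ± 0.777 CPM), the scavenger receptor Cd36 (53.9 ± 17.2 against 12.6 ± 1.09 CPM), the thioesterase Ppt1 (337 ± 54.2 against 161 ± 11.8 CPM) and Ifi205 (26.5 ± 14.5 against 4.77 ± 0.0522 CPM), and so did P2ry14 (4.88-fold). The lectin Mgl2 fell (1.86 ± 0.485 against 12.8 ± 2.45 CPM, adjusted p = 0.00408). Among cDC1 markers 5 of 28 rose (12 up and 1 down adjusted over the list alone, camera adjusted p = 1.94e-23). Among cDC2 markers 1 of 26 fell (3 adjusted over the list alone, camera adjusted p = 9.57e-07). In H/+ cDC2 only 4 genes passed, among them P2ry14 (10.3 ± 1.63 against 3.20 ± 0.926 CPM, adjusted p = 0.0227) and Cd36 (35.2 ± 5.47 against 12.6 ± 1.09 CPM, adjusted p = 0.00744). Among cDC1 markers 1 of 28 rose (5 up and 2 down adjusted over the list alone, camera adjusted p = 3.89e-05, adjusted p = 0.205 with an estimated correlation). The other fixed genes did not pass in H/H cDC2 (log2 fold changes from -0.24 to 0.72, adjusted p from 0.143 to 1), nor did any of the 12 in H/+ cDC2. The H/H test called 13 genes, 11 higher and 2 lower (6 higher and 9 lower with only the groups compared in the fit), 22 with a term for Xist libraries, 7 without WT cDC2 replicate 2 and 8 without H/H cDC2 replicate 2. The H/+ count of 4 was 17 with that term, 0 without WT cDC2 replicate 1 (edgeR, with 786 genes at an unadjusted p below 0.05) and 1 without H/+ cDC2 replicate 2, and DESeq2 called 32.

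The difference between the H/H effects in cDC1 and cDC2 was tested itself, a contrast added after the data were seen. For Irf8 the effects differed by -2.46 on the log2 scale (SE 0.186, adjusted p = 3.67e-06). The genes with the smallest p also included Cybb, Ms4a4c, Cd209a, Wfdc17 and Cd4, for which the H/H effect was higher in cDC1 (differences from 2.81 to 4.36, adjusted p from 6.63e-08 to 1.02e-05). Of the cDC2 markers 12 had a higher effect in cDC1 (18 adjusted over the list alone, camera adjusted p = 7.91e-27), and of the cDC1 markers 14 a lower one (18 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.04e-26). In all 307 genes differed, 226 with a higher and 81 with a lower effect in cDC1.

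An index of position was the mean log2 CPM of the cDC1 markers minus that of the cDC2 markers in each library. It was 5.96 ± 0.03 in WT cDC1 and -3.83 ± 0.06 in WT cDC2 (SD, n = 2). On the scale from WT cDC2 (0%) to WT cDC1 (100%), H/+ cDC1 lay at 91.2% ± 0.4 and H/H cDC1 at 82.3% ± 1.1, while H/+ cDC2 lay at 4.3% ± 2.1 and H/H cDC2 at 8.4% ± 2.8. Hybrid cells lay near the middle, at 41.1% ± 2.3 in H/+ and 49.5% ± 2.1 in H/H mice. In experiment 2, with no cDC2, the index was 6.18 ± 0.10 in WT cDC1, 3.77 ± 0.04 in H/H cDC1 and 0.60 ± 0.05 in H/H hybrid cells. It was 4.43 ± 0.01 in Nfil3-/- cDC1, 1.64 ± 0.09 in Nfil3-/- hybrid cells and 2.18 ± 0.14 in Zeb2 -165D123 hybrid cells. These positions are given as values with their spread, without a test.

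**Figure D3:**
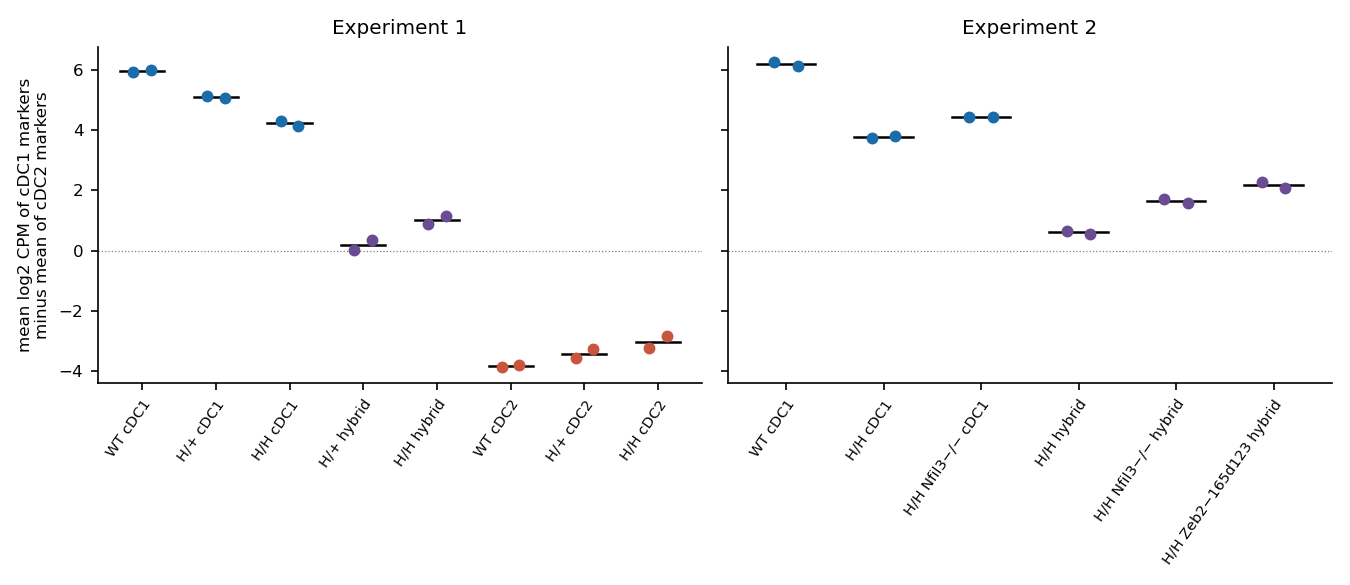
Mean log2 CPM of the cDC1 markers minus that of the cDC2 markers per library (points), for the groups of experiment 1 and experiment 2 in 2 panels, with a dotted line at 0. H/+ and H/H hybrid cells of experiment 1 had group means of 0.19 and 1.01, between 5.96 in WT cDC1 and -3.83 in WT cDC2.

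Hybrid cells were then compared with cDC1 and cDC2 of the same genotype. In H/+ hybrid cells cDC1 and cDC2 markers were expressed together, as the unstated gates may require. Xcr1 was 379.7 ± 30.2 CPM, against 753 ± 25.4 in H/+ cDC1 and 6.88 ± 1.09 in H/+ cDC2. Sirpa was 119 ± 11.2 CPM, against 2.22 ± 0.224 and 213 ± 11, and Zeb2 was 55.9 ± 17.9 CPM, against 2.62 ± 0.587 and 80.1 ± 6.42. Irf8, at 399 ± 7.85 CPM, was lower than in cDC1 (-1.53, adjusted p = 8.54e-07) and higher than in cDC2 (2.73, adjusted p = 4.65e-09). Cd8a, at 30.8 ± 2.2 CPM, lay nearer to cDC2 (18.6 ± 3.53), and Itgam, at 78.0 ± 16.5, did not pass the test against cDC2 (97.0 ± 14.7 CPM, log2 fold change -0.31, adjusted p = 0.294).

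Against H/+ cDC1, the largest rises in hybrid cells were in Clec4a4, Sirpb1c, Sirpb1a, Clec4a3, Pltp, Cyp4f37 and Tlr7 (109- to 343-fold), and Pram1 stood at 12.8 CPM against 2 counts over the cDC1 group. The largest falls included Cd8a, Clnk, Gpr33, Gcsam, Ttc39a, Dbn1 and Cd24a (6.35- to 8.59-fold). Irf4, Zeb2, Tcf4, Sirpa and Itgam rose (1.52- to 53.4-fold) and Id2 and Xcr1 fell (1.48- to 1.98-fold), while Batf3, Nfil3 and Zbtb46 did not pass (log2 fold changes from -0.24 to 0.16, adjusted p from 0.0802 to 0.788). Among cDC2 markers 23 of 26 rose (24 adjusted over the list alone, camera adjusted p = 1.54e-33). Among cDC1 markers 27 of 28 fell (28 adjusted over the list alone, camera adjusted p = 9.12e-28). Of the pattern recognition receptors 19 of 25 rose and 3 fell (20 and 3 adjusted over the list alone, camera adjusted p = 3.05e-11). Genes listed as monocyte and macrophage markers moved with them, since 11 of 16 rose and 2 fell (the same counts adjusted over the list alone, camera adjusted p = 8.6e-07, adjusted p = 0.0596 with an estimated correlation). However, 0 of these 16 passed as higher than both cDC1 and cDC2 in both genotypes (edgeR), though the means of 4 lay above both. A rise over cDC1 alone does not show other myeloid cells, since cDC2 held such transcripts too (C1qb 85.1 CPM in H/+ cDC2, 74.4 in H/+ hybrid cells). Of the neutrophil markers 6 of 7 rose (the same counts adjusted over the list alone, camera adjusted p = 2.63e-05, adjusted p = 0.06 with an estimated correlation). Against H/+ cDC2, the largest rises were in Clec4b2, Gcsam, Itgae (30.8 ± 8.84 against 0.379 ± 0.0477 CPM), Dkk3, Gpr141b, Xcr1, Gramd2 and Cd207 (40- to 259-fold). The largest falls were in Pde2a, Ryr3, Tmod2, Ttn, Mmp9, Scn3a, Cdhr3 and Igsf3 (13- to 67.3-fold). Batf3, Id2 and Cd8a were higher (1.53- to 2.09-fold) and Irf4, Tcf4, Zbtb46 and Sirpa lower (1.38- to 3.1-fold), while Zeb2 and Nfil3 did not pass (log2 fold changes from -0.52 to 0.28, adjusted p from 0.168 to 0.572). Among cDC1 markers 27 of 28 rose (the same counts adjusted over the list alone, camera adjusted p = 1.43e-38). Among cDC2 markers 3 of 26 rose and 11 fell (3 and 13 adjusted over the list alone, camera adjusted p = 0.000722, adjusted p = 0.0878 with an estimated correlation). Of the genes of MHC class I presentation 10 of 17 rose (13 adjusted over the list alone, camera adjusted p = 1.68e-08, adjusted p = 0.0538 with an estimated correlation). The tests called 2637 genes against cDC1 (1567 higher, 1070 lower) and 3046 against cDC2 (1650 higher, 1396 lower). Without H/+ hybrid replicate 2 they called 1683 and 1799.

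H/H hybrid cells of experiment 1 held less Zeb2 (40.1 ± 5.97 CPM) and Itgam (38.1 ± 1.39) than H/H cDC2 (77.4 ± 6.85 and 80.3 ± 1.66) and more than H/H cDC1 (4.78 ± 1.54 and 5.11 ± 0.0373). Irf8 was 562 ± 25.5 against 834 ± 4.26 CPM in cDC1 (-0.57, adjusted p = 0.0122) and 562 against 97.9 ± 16.4 CPM in cDC2 (adjusted p = 5.11e-09). Xcr1 was 465 ± 9.11 CPM, against 675 ± 25.8 in cDC1 and 9.00 ± 2.17 in cDC2, and Sirpa was 97.2 ± 8.04, against 6.49 ± 2.38 and 224 ± 19. Cd8a, at 14.7 ± 0.372 CPM, was lower than in both cDC1 (126 ± 12, adjusted p = 8.26e-09) and cDC2 (24.0 ± 0.782, adjusted p = 0.00207). Against cDC1, Clec4a4, Tlr7, Clec4a3, Sirpb1c, Sirpb1a, Pltp, Clec4a1 and Sirpb1b rose most (26.7- to 77.4-fold), and the largest falls besides Cd8a included Gcsam, Cd24a, Clnk, Dbn1, Septin3 and Ahnak (4.12- to 5.85-fold). Irf4 rose and Id2 and Xcr1 fell (1.31- to 1.45-fold), while Batf3, Nfil3, Zbtb46 and Tcf4 did not pass (log2 fold changes from -0.05 to 0.57, adjusted p from 0.212 to 0.83). Among cDC2 markers 22 of 26 rose (23 adjusted over the list alone, camera adjusted p = 8.44e-34). Among cDC1 markers 17 of 28 fell (20 adjusted over the list alone, camera adjusted p = 6.65e-20). Of the pattern recognition receptors 12 of 25 rose and 3 fell (17 and 3 adjusted over the list alone, camera adjusted p = 7.4e-10). Of the monocyte and macrophage markers 10 of 16 rose (12 adjusted over the list alone, camera adjusted p = 6.29e-12), with the complement gene C1qb 17.4-fold higher. Of the neutrophil markers 4 of 7 rose (5 adjusted over the list alone, camera adjusted p = 6.66e-06, adjusted p = 0.0501 with an estimated correlation).

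Against H/H cDC2, the hybrid cells held more Clec4b2, Dkk3, Gcsam, Gramd2, P3h2, Itgae (72.7 ± 6.46 against 0.705 ± 0.00635 CPM), Ptgis and Plce1 (55.7- to 195-fold). They held less Ryr3, Scn3a, the integrin chain Itgb3, Cdhr3, Dscam, Ncald, the Notch regulator Dtx1 (7.42 ± 2.26 against 132 ± 1.61 CPM) and Ripor2 (16.9- to 26.7-fold). Batf3, Id2 and Xcr1 were higher (1.68- to 51.5-fold), and Irf4, Zeb2, Zbtb46, Tcf4, Sirpa and Itgam lower (1.34- to 4.93-fold). Among cDC1 markers 26 of 28 rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 2.3e-30). Among cDC2 markers 3 of 26 rose and 16 fell (3 and 18 adjusted over the list alone, camera adjusted p = 1.16e-05), and of the genes of MHC class I presentation 13 of 17 rose (14 adjusted over the list alone, camera adjusted p = 5.7e-09). Of the ribosomal proteins 68 of 87 rose (79 adjusted over the list alone, camera adjusted p = 2.12e-18, adjusted p = 0.42 with an estimated correlation). The tests called 1259 genes against cDC1 (840 higher, 419 lower) and 4081 against cDC2 (2074 higher, 2007 lower). Without H/H cDC1 replicate 1 or 2 the first count was 765 and 568, and without H/H hybrid replicate 1 or 2 it was 623 and 645, while the second was 2521 and 2620 without those hybrid libraries and 2614 without H/H cDC2 replicate 1.

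Experiment 2 repeated H/H hybrid cells against H/H cDC1. Irf8 (341 ± 6.67 against 612 ± 50 CPM, adjusted p = 0.00078) and Cd8a (5.85 ± 0.901 against 86.7 ± 9.21 CPM) were lower in hybrid cells, with Gcsam, Dbn1, Cd24a, Clnk, Ttc39a and Septin3 (3.91- to 8.08-fold) and with Id2 and Xcr1 (1.37- to 1.48-fold). Zeb2 (42.8 ± 5.89 against 6.89 ± 0.463 CPM, adjusted p = 3.39e-05), Sirpa (183 ± 6.93 against 22.4 ± 0.638 CPM) and Itgam (58 ± 7.83 against 9.90 ± 1.43 CPM) were higher, with Clec4a3, Sirpb1a, Sirpb1c, Fcgr3, Tlr7, Pilra and Clec4a1 (24.7- to 64.5-fold). C1qb was 53.0 ± 15 against 1.68 ± 0.23 CPM, and of the monocyte and macrophage markers 10 of 17 rose (12 adjusted over the list alone, camera adjusted p = 1.41e-09, adjusted p = 0.0557 with an estimated correlation). Among cDC2 markers 22 of 26 rose (24 adjusted over the list alone, camera adjusted p = 7.3e-28). Among cDC1 markers 23 of 28 fell (26 adjusted over the list alone, camera adjusted p = 5.87e-23). Of the cell cycle genes 5 of 25 fell (the same counts adjusted over the list alone, camera adjusted p = 0.000303, adjusted p = 0.386 with an estimated correlation). Irf4 rose 2.16-fold, and Batf3, Nfil3, Zbtb46 and Tcf4 did not pass (log2 fold changes from -0.33 to 0.42, adjusted p from 0.0577 to 0.343). The test called 1811 genes, 1050 higher and 761 lower, 1155 and 1159 without H/H cDC1 replicate 1 or 2 and 852 and 696 without H/H hybrid replicate 1 or 2. Across the 14347 genes of both experiments the log2 fold changes had a Pearson correlation of 0.649 and a Spearman correlation of 0.596. Called in both were 580 genes higher (59.4 by chance), 242 lower (22.2 by chance) and 0 in opposite directions.

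The WT difference also gave a lineage signature of 1255 cDC1 genes and 2330 cDC2 genes (adjusted p of 0.05 and at least 2-fold), which was followed in contrasts that held no WT library. In H/+ hybrid cells 608 cDC1 signature genes (48.4%) were below H/+ cDC1 and 735 (58.6%) above H/+ cDC2. Of the cDC2 signature, 1086 genes (46.6%) were above H/+ cDC1 and 870 (37.3%) below H/+ cDC2. In H/H hybrid cells 248 cDC1 signature genes (19.8%) were below H/H cDC1 and 803 (64%) above H/H cDC2, while 652 cDC2 signature genes (28%) were above H/H cDC1 and 1101 (47.3%) below H/H cDC2. In experiment 2, 338 of 1217 tested cDC1 signature genes (27.8%) were below H/H cDC1 and 698 of 1868 cDC2 signature genes (37.4%) above it. Each of these shifts passed camera with an estimated correlation (adjusted p from 4.92e-06 to 0.0104). The signature was chosen on WT libraries of the same series, so its direction in H/+ and H/H cells is not evidence from another study.

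Few single genes differed between H/H and H/+ hybrid cells. In H/H hybrid cells the inhibitory receptor gene Clec4a4 (14.5 ± 0.0475 against 37.4 ± 4.62 CPM, adjusted p = 9.54e-05), Cd8a (14.7 ± 0.372 against 30.8 ± 2.2 CPM, adjusted p = 0.00508) and Tlr7 (14.6 ± 1.44 against 31.0 ± 0.347 CPM) were lower, as were Cyp4f37, Cd101, Bex6 and Ube2e2 (2.06- to 3.46-fold). Irf8 was 562 ± 25.5 against 399 ± 7.85 CPM (adjusted p = 0.32). Among cDC2 markers 2 of 26 fell (11 adjusted over the list alone, camera adjusted p = 1.49e-09). Among cDC1 markers 1 of 28 fell (12 up and 1 down adjusted over the list alone, camera adjusted p = 5.87e-11, adjusted p = 0.0596 with an estimated correlation). As lists, the WT cDC1 signature was higher in H/H hybrid cells (median 0.167 on the log2 scale, adjusted p = 0.00127 with an estimated correlation) and the WT cDC2 signature lower (median -0.201, adjusted p = 0.000785), though only 1 and 18 of their genes passed, all as lower. The remaining fixed genes did not pass (log2 fold changes from -1.04 to 0.31, adjusted p from 0.0695 to 0.955). The test called 21 genes lower and 0 higher (edgeR, of 1079 genes at an unadjusted p below 0.05 in either direction, with 23 higher by DESeq2). The total was 59 with a term for Xist libraries, 7 without H/+ hybrid replicate 2, and 11 and 3 without H/H hybrid replicate 1 or 2.

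**Figure D4:**
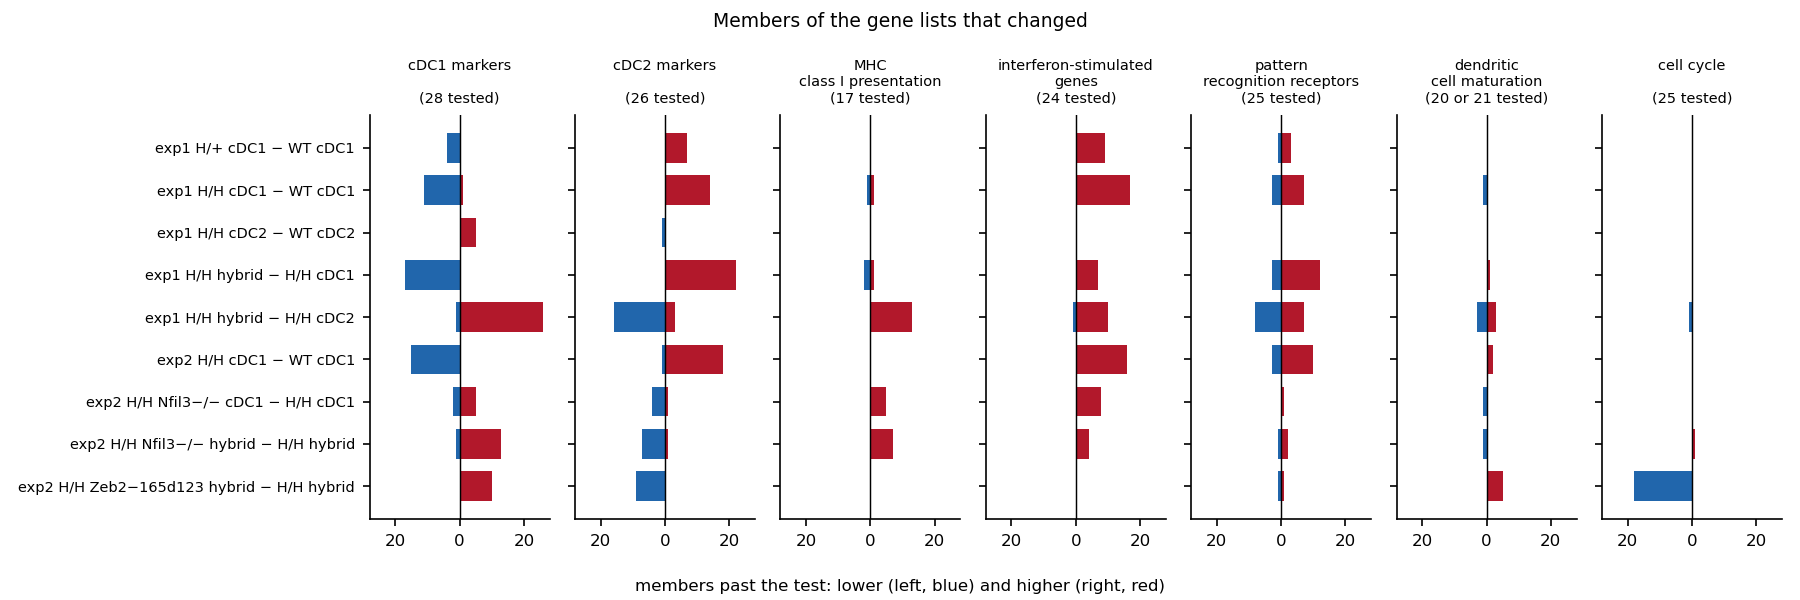
Members of 7 gene lists that passed the test, lower to the left (blue) and higher to the right (red), as counts of genes in 9 contrasts. In H/H cDC1 of experiment 1, 14 cDC2 markers and 17 interferon-stimulated genes were higher and 11 cDC1 markers lower.

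What does Nfil3 do in H/H cDC1? Without it, Itgae (299 ± 25.1 against 72.5 ± 9.91 CPM, adjusted p = 0.000105), the surface antigen Ly6a (414 ± 40 against 106 ± 4.42 CPM, adjusted p = 2.97e-06) and Xcr1 (707 ± 40.4 against 483 ± 4.57 CPM, adjusted p = 0.0142) rose, with the kinase Mapk13, Camk2b, Camkk1, Kdr, Upp1 and Tvp23a (3.61- to 7.56-fold). Cd8a fell from 86.7 ± 9.21 to 31.0 ± 8.53 CPM (adjusted p = 0.00655). The lectins Cd209a (14.0 ± 2.02 against 289 ± 162 CPM) and Cd209e, the pyrin gene Mefv, Hpgd, Zbtb10 and Serpinb2 also fell (4.16- to 20.5-fold). Irf8 and Zeb2 did not pass, nor did the other fixed genes (log2 fold changes from -0.67 to 0.24, adjusted p from 0.134 to 0.986). Among cDC1 markers 5 of 28 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.000445, adjusted p = 0.297 with an estimated correlation). Among cDC2 markers 1 of 26 rose and 4 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.00105, adjusted p = 0.0571 with an estimated correlation). Of the genes of MHC class I presentation 5 of 17 rose (7 adjusted over the list alone, camera adjusted p = 1.38e-07, adjusted p = 0.0875 with an estimated correlation). Of the interferon-stimulated genes 8 of 24 rose (14 adjusted over the list alone, camera adjusted p = 2.17e-14, adjusted p = 0.217 with an estimated correlation). Markers of other cells were higher in the same libraries, since of the neutrophil markers 3 of 11 rose (8 adjusted over the list alone, camera adjusted p = 1.17e-09, adjusted p = 0.129 with an estimated correlation) and of the erythroid markers 2 of 10 rose (9 adjusted over the list alone, camera adjusted p = 6.64e-10, adjusted p = 0.153 with an estimated correlation). The test called 440 genes, 195 higher and 245 lower. H/H libraries held no Xist while 1 of 2 Nfil3-/- libraries did, and the count was 311 with a term for this, 148 without the Xist libraries, 191 without H/H cDC1 replicate 1, and 264 and 167 without Nfil3-/- cDC1 replicate 1 or 2. The balance of directions did not hold, with 92 higher and 56 lower without the Xist libraries and 98 higher and 69 lower without Nfil3-/- cDC1 replicate 2. Without the Xist libraries, 1 gene of MHC class I presentation passed as higher (median 0.27, against 0.23 in all libraries), 4 interferon-stimulated genes as higher (0.64, against 0.74) and 2 cDC2 markers as lower (-0.46, against -0.49). No erythroid call stayed, with 0 genes (edgeR) under a term for Xist libraries and 0 without them, at medians of 2.94 and 2.29 against 3.3. Over the lineage signature from WT cells, 51 of 1217 cDC1 genes rose and 56 fell (camera adjusted p = 0.753). Of 1868 cDC2 genes 58 rose and 88 fell (camera adjusted p = 0.0206, adjusted p = 0.173 with an estimated correlation).

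In hybrid cells without Nfil3 several cDC1 markers were higher and several cDC2 markers lower. Itgae rose from 51.3 ± 1.04 to 349 ± 85.3 CPM (adjusted p = 7.34e-06), Xcr1 from 352 ± 34.4 to 585 ± 26.2 (adjusted p = 0.00171), Gpr33 from 1.32 ± 0.669 to 10.7 ± 1.47 (adjusted p = 0.000137) and Id2 1.45-fold (adjusted p = 0.0478). Itgam fell to 32.4 ± 4.08 from 58 ± 7.83 CPM (adjusted p = 0.0245), and Zeb2 stood at 23.7 ± 5.87 against 42.8 ± 5.89 CPM (adjusted p = 0.0804) and Irf8 at 436 ± 2.42 against 341 ± 6.67 CPM (adjusted p = 0.154). The macrophage elastase Mmp12, the lysozyme Lyz1, Cd209b, Cd209e, Col27a1, Cacna1e and P3h2 fell (4.97- to 26.3-fold). Besides Itgae and Gpr33 the largest rises were in Upp1, the neutrophil granule gene Ltf, Abca13, Camk2b, the interferon-inducible GTPase Tgtp1 and Fndc5 (4.94- to 37.9-fold). Among cDC1 markers 13 of 28 rose and 1 fell (18 and 2 adjusted over the list alone, camera adjusted p = 2.14e-12, adjusted p = 0.0818 with an estimated correlation). Among cDC2 markers 1 of 26 rose and 7 fell (2 and 13 adjusted over the list alone, camera adjusted p = 0.000157). Of the genes of MHC class I presentation 7 of 17 rose (12 adjusted over the list alone, camera adjusted p = 1.39e-09, adjusted p = 0.062 with an estimated correlation), of the interferon-stimulated genes 4 of 24 rose (12 adjusted over the list alone, camera adjusted p = 1.39e-07, adjusted p = 0.386 with an estimated correlation). Of the neutrophil markers 3 of 11 rose (8 adjusted over the list alone, camera adjusted p = 1.97e-06, adjusted p = 0.211 with an estimated correlation). Batf3, Irf4, Zbtb46, Tcf4, Cd8a and Sirpa did not pass (log2 fold changes from -0.95 to 0.32, adjusted p from 0.126 to 0.319). The test called 540 genes, 280 higher and 260 lower, with 385 under a term for Xist libraries and 178 without them. It called 215 and 127 (59 higher, 68 lower) without H/H hybrid replicate 1 or 2, and 223 and 184 without Nfil3-/- hybrid replicate 1 or 2. Without the Xist libraries fewer list members passed while the medians stayed near those of all libraries. These were 6 cDC1 markers higher (median 0.51, against 0.44), 1 cDC2 marker lower (-0.65, against -0.54) and 1 gene of MHC class I presentation higher (0.37, against 0.38). With a term for Xist libraries 2 interferon-stimulated genes passed as higher (0.31, against 0.57). Over the lineage signature from WT cells, 95 of 1217 cDC1 genes rose and 38 fell (camera adjusted p = 0.00235, adjusted p = 0.219 with an estimated correlation), while 27 of 1868 cDC2 genes rose and 114 fell (adjusted p = 0.0299 with an estimated correlation). Both Nfil3-/- hybrid libraries also differed in signs of quality from both H/H hybrid libraries. Mitochondrial genes took 1.01 and 0.94% of counts, against 1.58 and 1.54%, and ribosomal RNA 0.967 and 1.027%, against 1.911 and 2.287%. Of the mitochondrially encoded genes 1 of 16 fell (10 adjusted over the list alone, camera adjusted p = 1.41e-06, adjusted p = 0.405 with an estimated correlation). How far this difference between libraries shaped the other changes was not tested.

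The Nfil3 effects in hybrid cells and in cDC1 were compared by an interaction contrast. Only Tgm2 passed, with an effect lower in hybrid cells by -1.22 on the log2 scale (SE 0.167, adjusted p = 0.0245). The other genes with the smallest p did not pass, among them Lrp1 (-1.35), Lyz1 (-1.18), Clnk (1.19), Clec4b2 (0.96), Gcnt2 (1.41), Ttc39a (1.00) and Kdr (-1.52), with adjusted p from 0.436 to 1. Of the cDC1 markers 0 passed (edgeR), though as a list their effect was higher in hybrid cells (camera adjusted p = 9.19e-12, adjusted p = 0.0875 with an estimated correlation). At an unadjusted p below 0.05 there were 510 genes, and DESeq2 called 3. The call did not hold when libraries were left out. Tgm2 passed without H/H cDC1 replicate 1 (2 genes), but edgeR called 0 genes without Nfil3-/- cDC1 replicate 2, either H/H hybrid replicate, or Nfil3-/- hybrid replicate 2. Without H/H cDC1 replicate 2, Nfil3-/- cDC1 replicate 1 or Nfil3-/- hybrid replicate 1 it called 1 gene, which was not Tgm2.

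Nfil3-/- hybrid cells still differed from Nfil3-/- cDC1. Zeb2 (23.7 ± 5.87 against 4.91 ± 0.205 CPM, adjusted p = 0.000257), Sirpa (134 ± 6.55 against 15.6 ± 1.32 CPM) and Itgam (32.4 ± 4.08 against 7.41 ± 2.29 CPM) were higher, with Clec4a3, Clec4a1, Sirpb1c, Pilra, Fcgr3 and Cd209a (18.3- to 96-fold) and Irf4 (2.21-fold). Cd8a (3.03 ± 0.163 against 31.0 ± 8.53 CPM), Gcsam, Cd24a, Dbn1, Ahnak, P3h2 and Dkk3 were lower (2.99- to 10.2-fold), and Irf8 was 436 ± 2.42 against 615 ± 98.3 CPM (adjusted p = 0.0476). Among cDC2 markers 22 of 26 rose (24 adjusted over the list alone, camera adjusted p = 1.37e-37). Among cDC1 markers 10 of 28 fell (15 adjusted over the list alone, camera adjusted p = 3.29e-16, adjusted p = 0.0557 with an estimated correlation). The complement genes C1qb and C1qa rose (18.3- to 37.3-fold), and of the monocyte and macrophage markers 11 of 17 rose (the same counts adjusted over the list alone, camera adjusted p = 1.88e-14). The residual Nfil3 transcript was 5.66 ± 0.0537 against 3.22 ± 0.654 CPM, and Batf3, Id2, Zbtb46, Tcf4 and Xcr1 did not pass (log2 fold changes from -0.27 to 0.33, adjusted p from 0.157 to 0.715). The test called 766 genes, 583 higher and 183 lower. Without Nfil3-/- cDC1 replicate 2 the count was 347, without Nfil3-/- hybrid replicate 1 or 2 it was 415 and 393, and without the Xist libraries it was 207.

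The last comparison asked what the Zeb2 enhancer contributes in H/H hybrid cells. With the altered enhancer, Zeb2 was 14.9 ± 6.55 against 42.8 ± 5.89 CPM (-1.51, adjusted p = 0.00553) and Irf8 was 498 ± 29 against 341 ± 6.67 CPM (0.55, adjusted p = 0.0357). The cDC1 markers Cd8a (25.4 ± 9.93 against 5.85 ± 0.901 CPM, adjusted p = 0.00181), Itgae (212 ± 63.7 against 51.3 ± 1.04 CPM) and Gcsam (86.0 ± 11.3 against 19.8 ± 1.74 CPM) and the adaptor Clnk (19.4 ± 0.217 against 2.77 ± 0.0746 CPM) rose. The chemokine receptors Ccr2 (8.10 ± 0.406 against 62.5 ± 2.62 CPM, adjusted p = 3.78e-08) and Cx3cr1 (1.18 ± 0.197 against 8.77 ± 1.88 CPM) fell, as did the peptidase Ace, Lyz1, Sirpb1c, Stat4, Ccl9, Abca9 and Cd7 (4.06- to 37.7-fold). Other rises were in Upp1, the complement component C6, Abca13, Fcna, Ccr3, Cd5l and Slc45a3 (7.36- to 18.8-fold). Cell cycle genes were lower, since 18 of 25 fell (24 adjusted over the list alone, camera adjusted p = 9.08e-26, adjusted p = 0.0557 with an estimated correlation), with Mki67, Bub1, Ccna2 and Top2a falling by 1.98- to 2.3-fold. Among cDC1 markers 10 of 28 rose (18 adjusted over the list alone, camera adjusted p = 6.02e-17, adjusted p = 0.0557 with an estimated correlation). Among cDC2 markers 9 of 26 fell (15 adjusted over the list alone, camera adjusted p = 2.14e-12). Markers of macrophages moved with these groups, since of the monocyte and macrophage markers 5 of 17 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.000122, adjusted p = 0.161 with an estimated correlation), with the complement genes C1qc and C1qa and the receptor Mertk 4.08- to 6.82-fold higher. Of the maturation genes 5 of 20 rose (the same counts adjusted over the list alone, camera adjusted p = 4.43e-06, adjusted p = 0.33 with an estimated correlation), and of the immediate early and heat shock genes 4 of 21 rose (the same counts adjusted over the list alone, camera adjusted p = 0.00134, adjusted p = 0.293 with an estimated correlation). Batf3, Irf4, Nfil3, Id2, Zbtb46, Tcf4, Xcr1, Sirpa and Itgam did not pass (log2 fold changes from -0.34 to 0.50, adjusted p from 0.0557 to 0.993). The test called 583 genes, 323 higher and 260 lower, with 471 under a term for Xist libraries and 213 without them, where 4 cell cycle genes passed as lower (median -0.75, against -0.81 in all libraries), 5 cDC1 markers as higher (0.58, against 0.51) and 6 cDC2 markers as lower (-0.59, against -0.69). Without them 2 maturation genes passed as higher (0.28, against 0.34) and 0 immediate early and heat shock genes (edgeR, median 0.41, against 0.26). It called 127 and 253 (95 higher, 158 lower) without H/H hybrid replicate 1 or 2, and 260 and 208 without Zeb2 -165D123 hybrid replicate 1 or 2. Over the lineage signature from WT cells, 118 of 1217 cDC1 genes rose and 12 fell (camera adjusted p = 3.75e-10, adjusted p = 0.0557 with an estimated correlation). Of 1868 cDC2 genes 69 rose and 82 fell (camera adjusted p = 0.0975). Of the cDC2 genes at least 4-fold apart in WT cells, 46 of 923 rose and 71 fell (adjusted p = 0.019 with an estimated correlation), and of such cDC1 genes 77 of 482 rose (adjusted p = 0.00275). Signs of quality differed here too. Mitochondrial genes took 1.38 and 1.05% of counts in the Zeb2 -165D123 hybrid libraries, against 1.58 and 1.54% in the H/H hybrid libraries. Ribosomal RNA took 1.654 and 1.442%, against 1.911 and 2.287%. How far this shaped the other changes was not tested.

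**Figure D5:**
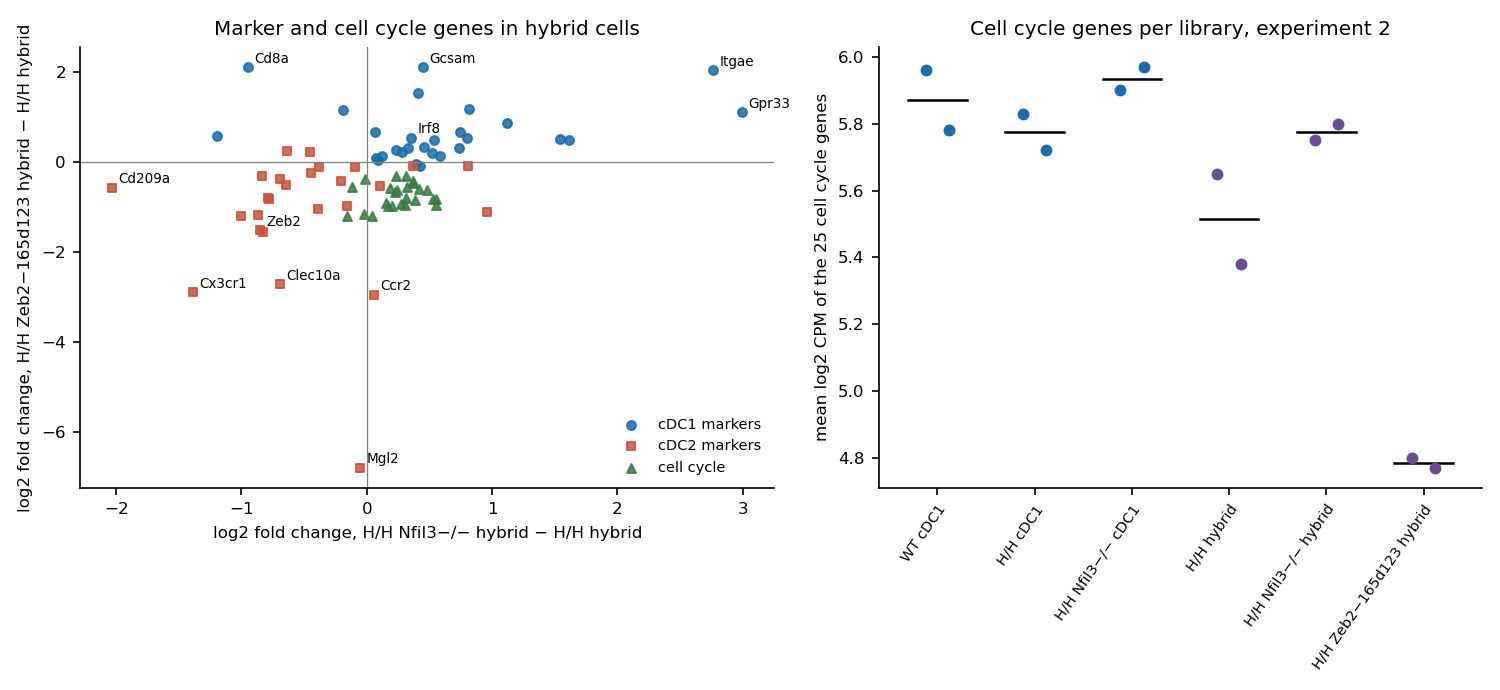
Left, log2 fold change of each gene in Nfil3-/- hybrid cells (x axis) and Zeb2 -165D123 hybrid cells (y axis) against H/H hybrid cells, for cDC1 markers (circles), cDC2 markers (squares) and cell cycle genes (triangles). Right, mean log2 CPM of the 25 cell cycle genes per library of experiment 2 with the group mean (line), where 18 of these genes were lower in Zeb2 -165D123 hybrid cells and 0 in Nfil3-/- hybrid cells.

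The Nfil3 and Zeb2 effects in hybrid cells were compared across 14504 genes, which are not independent replicates. Of the genes higher in Nfil3-/- (280) and in Zeb2 -165D123 hybrid cells (323), 49 were shared, against 6.24 if the lists were independent, and of those lower (260 in each) 25 were shared, against 4.66. In opposite directions 19 genes passed. The Pearson correlation of the log2 fold changes was 0.363, the Spearman correlation 0.282 and the covariance 0.183. Because both effects share the same 2 control libraries, 30 pairs of simulated unchanged groups gave a correlation of 0.509 (0.458 to 0.551) and a covariance of 0.106, with 0.033 shared higher genes on average. The covariance lay above the simulated mean by 0.077. The simulated groups held no effects of their own, which change a correlation, so the Pearson values cannot be compared and no conclusion is drawn from them. Each altered hybrid group also held 1 Xist library, while the H/H hybrid libraries held no Xist, which the simulation left out. How many shared genes follow from this was not tested.

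The remaining lists cover cells that a sort can leave behind and general functions of the cell. In WT cDC1 against cDC2, of the B cell markers 2 of 10 rose and 6 fell (the same counts adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.133 with an estimated correlation), of the T cell markers 4 of 11 fell (3 adjusted over the list alone, camera adjusted p = 0.115), of the NK cell markers 1 of 5 rose and 2 fell (the same counts adjusted over the list alone, camera adjusted p = 0.829) and of the pDC markers 2 of 17 rose and 10 fell (the same counts adjusted over the list alone, camera adjusted p = 0.00564, adjusted p = 0.0958 with an estimated correlation). Of the platelet and megakaryocyte markers 1 of 4 rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 0.816) in H/+ hybrid cells against cDC1. In the same contrast, of the dendritic cell transcription factors 11 of 27 rose and 4 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.381 with an estimated correlation), of the genes for uptake of dead cells 6 of 14 rose and 3 fell (the same counts adjusted over the list alone, camera adjusted p = 0.105), and of the chemokines and migration receptors 8 of 24 rose and 4 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.363 with an estimated correlation). In WT cDC1 against cDC2, of the MHC class II genes 4 of 14 rose and 6 fell (the same counts adjusted over the list alone, camera adjusted p = 0.435), of the C/EBP family 4 of 6 fell (the same counts adjusted over the list alone, camera adjusted p = 0.287), and of the mitochondrially encoded genes 2 of 17 rose (0 adjusted over the list alone, camera adjusted p = 0.223).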

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

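Of the tests in this part, those on carried over cells, on mixtures, on macrophages and on dilution, and the contrast of the H/H effects in cDC1 and cDC2, were chosen only after the results were seen.

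The H/H allele acted differently on the 2 lineages, as tested by the difference between its effects in cDC1 and cDC2. For Irf8 this difference was -2.46 on the log2 scale, with lower Irf8 in 2 of 2 H/H cDC1 libraries and higher Irf8 in 2 of 2 H/H cDC2 libraries than in both WT libraries. In all 307 genes differed. A difference between the Nfil3 effects in hybrid cells and cDC1 also passed for 1 gene, Tgm2 (-1.22, adjusted p = 0.0245). Of the 8 fits that left out 1 library, Tgm2 passed only without H/H cDC1 replicate 1. In the other 7 edgeR called 0 genes (without Nfil3-/- cDC1 replicate 2, either H/H hybrid replicate or Nfil3-/- hybrid replicate 2) or 1 other gene. In all libraries 510 genes had an unadjusted p below 0.05, and DESeq2 called 3.

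Hybrid cells expressed cDC1 and cDC2 markers together, which the gates, or a mixture or doublets of cDC1 and cDC2 cells in the hybrid gate, could also give. A mixture holds no transcript beyond both of its parts, yet 63 genes lay at least 1.5-fold beyond both parents in H/+ and in H/H hybrid cells, past the threshold in all 4 contrasts, against at most 1 in 20 simulated mixtures, which argues against these parents as the whole source. Monocytes or macrophages in the gate cannot be told apart, since 0 of 16 of their markers were higher in all 4 contrasts (edgeR), but only 1 was below 1 CPM in both parents, so that levels in cDC2 (C1qb 90.5 CPM, against 78.0 in H/H hybrid cells and 4.45 in cDC1) could hide a share. Means above both parents in both genotypes were seen for 4 of the markers, namely Hmox1 (151 CPM in H/H hybrid cells, 89.6 in cDC1 and 66.3 in cDC2), Cd14, Spic and Vcam1. These cells, others that were not sorted here, and a cell state of its own stay open.

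cDC2 markers were higher in H/H cDC1, 14 in experiment 1 and 18 in experiment 2, and hybrid cells carried over into the cDC1 gate could give this. The rise of these markers needs a median share of 17.7% hybrid cells (3 to 53.4%) in experiment 1 and of 20.2% (3.7 to 95.5%) in experiment 2. Of transcripts with at least 10 CPM in hybrid cells and at most 1 CPM in WT cDC1, 46.5% of 43 and 33.9% of 56 stayed below 0.5 of the level that this share needs, so carry-over cannot be told apart from a change within cDC1 by this test, which lay between its bounds. In both H/H cDC1 libraries, 7 and 5 such transcripts had a share below that of every raised marker. Those markers were chosen as higher, which sets a floor under their shares, so this count cannot decide. Shares of all such transcripts ran from -1.27 to 34.0% and from -1.24 to 48.7% (Sirpb1a 2.27 and 3.17%, Nxpe4 20.6 and 29.1%). Carry-over at 1 share as the only source would give 1 value, so this spread argues against it for these transcripts. Cells at the border of the gates with another profile, which the unstated gates might let through, also stay open.

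Cell cycle genes were lower in Zeb2 -165D123 hybrid cells, a median of -0.81 on the log2 scale with 18 of 25 past the threshold. Dilution by cells of another type that do not divide could lower them and cannot be told apart, since the cDC1 markers that it would lower as well (median 0.51) were raised in the same contrast, and 5 of 17 monocyte and macrophage markers rose too (C1qc and C1qa 4.33- to 6.82-fold). With a term for the Xist library of this group 14 genes still passed (median -0.73). Without the Xist libraries the median was -0.75 and 4 genes passed, in a smaller fit with fewer degrees of freedom, so that library is argued against as the source of the change. Dilution stays open, as do a lower share of dividing cells within the hybrid population and the age or state of single mice, which were not tested.

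For the 2 contrasts made in both experiments, a fit of all 8 libraries with a term for the experiment gave 1538 genes for H/H against WT cDC1. The highest count among the other splits of these libraries within the experiments was 0 (edgeR). For H/H hybrid cells against H/H cDC1 the fit gave 3231 genes, and the highest other split gave 1. In both cases there are only 18 such splits, too few for a share under 0.05.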

How the results depend on the processing

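Of the alternatives, the term for Xist libraries and leaving out the 3 Xist libraries of experiment 2 were chosen only after the data were seen. Counts are of genes past adjusted p 0.05, and a count is taken as kept when it stayed within 1.5 times the value in the report.

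The 5 contrasts added after the data were seen were not fitted under alternatives. No gene named for the 17 planned contrasts reversed. Every count of these 17 was kept with RLE factors and with the filter at 1 CPM, and 0 genes were called in opposite directions by the report's edgeR fit and any alternative. For the genes named in the report, in the planned contrasts, 18328 of 21094 values under alternatives stayed on the same side of the threshold in the same direction, 2681 lost the call, 85 gained it and 0 reversed.

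The balance of higher and lower calls did not hold everywhere. H/H cDC2 gave 6 higher and 9 lower with only the groups compared. Nfil3 in cDC1, mostly lower in the report, gave 306 higher and 300 lower with DESeq2, 156 and 150 with only the groups compared, 275 and 247 without H/H cDC1 replicate 2, 98 and 69 without Nfil3-/- cDC1 replicate 2 and 92 and 56 without the Xist libraries. Nfil3 in hybrid cells gave 232 and 237 with a replicate block and 59 and 68 without H/H hybrid replicate 2, where Zeb2 gave 95 and 158. Hybrid against cDC2 cells, mostly higher in the report, had slightly more lower calls under glmTreat (477 and 481 in H/+, 629 and 736 in H/H). This was also so with only the groups compared in H/+ (1094 and 1107). In H/H cells it was so without a filter (2013 and 2108), with a replicate block (2317 and 2348), with a block within genotype (2322 and 2352) and without H/H cDC2 replicate 1 (1299 and 1315). The cause was not tested.

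A test against a 1.5-fold change (glmTreat), which asks for more by construction, lowered all 17 counts. It called 3373 genes in WT cDC1 against cDC2, 22 and 0 in H/+ cDC1 and cDC2 (168 genes at an unadjusted p below 0.05 for the latter), 174 and 7 in H/H cDC1 and cDC2, 901 and 958 in H/+ hybrid cells against cDC1 and cDC2, 1365 and 376 in H/H hybrid cells against cDC2 and cDC1, and 4 in H/H against H/+ hybrid cells. In experiment 2 it called 286 in H/H cDC1, 350 in H/H hybrid cells against cDC1, 83, 92 and 93 for Nfil3 in cDC1, Nfil3 in hybrid cells and Zeb2, 215 in Nfil3-/- hybrid cells against cDC1 and 0 in the interaction (162 unadjusted).

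DESeq2 moved 6 counts, to 563 and 32 in H/+ cDC1 and cDC2, 34 in H/H cDC2, 76 in H/H against H/+ hybrid cells, 873 for Nfil3 in hybrid cells and 3 in the interaction. Without a filter 9 counts moved, to 673 and 83 in H/+ cDC1 and cDC2, 1051 and 79 in H/H cDC1 and cDC2, 153 in H/H against H/+ hybrid cells, 772, 1050 and 900 for Nfil3 in cDC1, Nfil3 in hybrid cells and Zeb2, and 23 in the interaction. With only the groups compared in the fit, H/+ cDC1 gave 41, H/+ cDC2 0 (754 unadjusted), H/+ hybrid against cDC1 1733, H/H against H/+ hybrid cells 43, H/H cDC1 in experiment 2 548 and Nfil3 in hybrid cells 1953. The cause was not tested.

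The labels do not say whether numbers pair cells of 1 animal. With a replicate block, which in experiment 1 is the same model as the term for Xist libraries, counts moved to 597 and 17 in H/+ cDC1 and cDC2, 22 in H/H cDC2, 59 in H/H against H/+ hybrid cells and 0 in the interaction (447 unadjusted). A block within genotype gave 1280 for Nfil3-/- hybrid cells against cDC1. Residuals of libraries with the same number and genotype correlated at 0.022 to 0.294 in experiment 1 (7 pairs of groups) and 0.084 to 0.157 in experiment 2 (2 pairs), and those of different genotype at -0.04 to 0.219 and -0.205 to 0.052. Without the 3 Xist libraries counts were 148, 178 and 213 for Nfil3 in cDC1, Nfil3 in hybrid cells and Zeb2, 0 in the interaction (364 unadjusted) and 207 in Nfil3-/- hybrid cells against cDC1, with fewer libraries. Both experiments in 1 fit, with more libraries, gave 1538 for H/H cDC1 and 3231 for H/H hybrid cells against cDC1.

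Leaving out each library in turn leaves 1 library in a group, which is assumed to vary like the other groups. The counts ranged from 5465 to 5637 in WT cDC1 against cDC2, 59 to 457 and 0 to 5 in H/+ cDC1 and cDC2, 328 to 437 and 7 to 18 in H/H cDC1 and cDC2, 1683 to 2343 and 1799 to 2234 in H/+ hybrid cells against cDC1 and cDC2, 568 to 765 and 2521 to 3052 in H/H hybrid cells against the same, and 3 to 17 in H/H against H/+ hybrid cells. In experiment 2 they ranged from 571 to 702 in H/H cDC1, 696 to 1159 in H/H hybrid cells against cDC1, 167 to 522 and 127 to 223 for Nfil3 in cDC1 and hybrid cells, 127 to 260 for Zeb2, 0 to 2 in the interaction and 347 to 516 in Nfil3-/- hybrid cells against cDC1.

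Of the gene list tests, 105 of 240 in experiment 1 and 86 of 168 in experiment 2 passed with camera, 22 and 7 with an estimated correlation, and 97 and 51 with fry. All 12 shifts of the lineage signature (2 of them in Nfil3-/- hybrid cells against cDC1) were kept at 4-fold and with an estimated correlation. Positions on the scale from WT cDC2 (0%) to WT cDC1 (100%) from list medians were 89.7% in H/+ cDC1, 34.1% in H/+ hybrid cells, 74.7% in H/H cDC1 and 41.3% in H/H hybrid cells. From WT signature genes they were 87.4%, 44.6%, 80.4% and 52.6%, with 2.1% in H/+ and 4.4% in H/H cDC2. Among genes at 10 CPM or more the Pearson correlation between experiments was 0.859 for H/H cDC1 and 0.862 for H/H hybrid cells against cDC1, higher than over all genes. The cause was not tested. For the Nfil3 and Zeb2 effects it was 0.456 among these genes, within the range of the simulated pairs (0.353 to 0.652), while the covariance stayed above their mean by 0.044. These pairs held no effects of their own, so the correlation cannot decide on agreement. Depth limits the genes at few counts, since a group with 0 counts allows up to 0.0536 CPM in WT cDC1, and changes below that level cannot be seen.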

Other observations

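The contrasts and gene counts of this part were chosen only after the data were seen, and no explanation is offered for them.

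Genes outside the range between cDC1 and cDC2 set hybrid cells apart. At least 1.5-fold above both cDC1 and cDC2 of the same genotype, past the threshold in both contrasts, were 101 genes in H/+ and 80 in H/H hybrid cells (51 in both genotypes). Below both lay 42 and 28 (12 in both genotypes). The lectin genes Clec1b (110.3 CPM in H/+ hybrid cells, 6.48 in cDC1 and 5.61 in cDC2) and Cd209a (1048, 77.3 and 457) were above both, as were the lipoprotein gene Apoe (390, 167 and 151) and the chemokine gene Ccl6 (303, 94.4 and 65.9). In H/H cells the order was the same for Clec1b (82.1, 7.74 and 4.28), Cd209a (866, 137 and 421) and Apoe (619.9, 219 and 177). Among signature genes that differed between both parents, hybrid cells lay at a median of 47.8% of the way from cDC2 to cDC1 in H/+ (quartiles 31.1 and 66.2, 945 genes, 60 of them beyond cDC2 and 26 beyond cDC1) and 67% in H/H mice (48.6 and 84.3, 894 genes, 42 and 64 beyond).

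Few genes separated H/H from H/+ cDC1. Against H/+ cDC1, H/H cDC1 held more Cybb (65.9 ± 5.49 against 19.6 ± 5.15 CPM), Gpr183 (121 ± 4.99 against 56.2 ± 10 CPM), Ms4a4c, Skint3, Tgm2, Cd300lf and Wfdc17, and more Sirpa (6.49 ± 2.38 against 2.22 ± 0.224 CPM). Cd8a (126 ± 12 against 265 ± 38 CPM), Cd207 (15.8 ± 3.75 against 47.6 ± 7.86 CPM) and Igf2r were lower. Of the cDC2 markers 5 of 26 rose (12 adjusted over the list alone, camera adjusted p = 7.32e-18), and of the interferon-stimulated genes 2 of 24 rose (14 adjusted over the list alone, camera adjusted p = 4.45e-25, adjusted p = 0.0813 with an estimated correlation). The edgeR test called 45 genes, 35 higher and 10 lower. In cDC2 the same step gave 0 genes (edgeR, 521 at an unadjusted p below 0.05), while the cDC1 markers as a list were higher (camera adjusted p = 1.03e-13, 0.0474 with an estimated correlation).

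The Nfil3 and Zeb2 alterations differed in hybrid cells for 1583 genes, 757 higher and 826 lower in Nfil3-/- cells. Ccr2 (65 ± 4.78 against 8.10 ± 0.406 CPM), Sirpb1c, Spon1 and Ltf were higher in Nfil3-/- hybrid cells, and Cd8a (3.03 ± 0.163 against 25.4 ± 9.93 CPM), Fcna (5.44 ± 5.46 against 78.6 ± 5.1 CPM), C6, Ccr3 and Cldn1 were lower. Of the cell cycle genes 23 of 25 rose (25 adjusted over the list alone, camera adjusted p = 2.65e-26, adjusted p = 0.0624 with an estimated correlation), of the maturation genes 11 of 20 fell (the same counts adjusted over the list alone, camera adjusted p = 2.72e-09, adjusted p = 0.184 with an estimated correlation), and of the cDC2 markers 9 of 26 rose and 1 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.0999 with an estimated correlation). Against H/H cDC1, Zeb2 -165D123 hybrid cells still held more Sirpa (155 ± 6.33 against 22.4 ± 0.638 CPM), C1qa, C1qb, C1qc and Slpi and less Cd8a (25.4 ± 9.93 against 86.7 ± 9.21 CPM), and 3055 genes differed (1669 higher, 1386 lower). Of the monocyte and macrophage markers 11 of 17 rose (the same counts adjusted over the list alone, camera adjusted p = 9.81e-11, adjusted p = 0.0624 with an estimated correlation), and of the erythroid markers 10 of 10 rose (the same counts adjusted over the list alone, camera adjusted p = 2.37e-07, adjusted p = 0.184 with an estimated correlation). Nfil3 itself stood at higher values in the Nfil3-intact groups of experiment 2 (from 33.9 CPM in WT cDC1 to 48.6 in Zeb2 -165D123 hybrid cells) than in the groups of experiment 1 (from 7.25 in H/H cDC1 to 10.7 in H/H hybrid cells).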
